A study of Mus musculus with 6 samples.

How the data were processed

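Total RNA was measured by sequencing in 6 libraries of CGR8 cells, a mouse embryonic stem cell line, grown in medium with 10% fetal bovine serum and LIF. Per the labels' protocols, the cells were transfected with siRNA pools and collected after 48 hours, RNA was extracted with TRIzol, ribosomal RNA was depleted, and libraries were made with a stranded total RNA kit. The groups were taken from the siRNA label: 3 libraries with a non-targeting pool (siCtrl) and 3 with a pool against Rsl24d1 (siRSL24D1). The series' design text calls them independent triplicates.

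The deposited table holds estimated counts per gene symbol and library, not scaled between libraries. Per the submitters' processing notes, the tools were STAR 2.7.0f and Salmon 0.14.1 and the genome build was GRCm38. The role of each tool, the annotation release, the filters, the strand setting of the counting and the way transcripts were summed to genes are not given in the sources used here. Between 21.59% and 22.65% of the values of a library were not whole numbers, at a tolerance of 1e-09. The table lists 22332 symbols, of which 22304 were found in GENCODE M21 and 21779 are protein-coding there. No count was recorded in any library for 2592 of them. Library totals ran from 30943635 to 35214000 estimated counts, and all 6 columns were used.

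The tests had been planned for counts; since the values are estimated counts, they were rounded to whole numbers first. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 15084 genes. Libraries were scaled by TMM, and siRSL24D1 was compared with siCtrl by the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with no other term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called past the test at an adjusted p under 0.05. Levels are TMM-scaled CPM (counts relative to the scaled library total of the genes kept by the filter), computed from the rounded counts and given as mean ± SD over 3 libraries. The CPM limits in the receptor and silent-gene tests were applied to unrounded values over full library totals, without TMM scaling. Fold changes are siRSL24D1 over siCtrl. Common biological variation in the fit was 7.48%.

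Before the data were examined, 24 gene lists with 644 distinct genes and no shared member were fixed, together with the tests, the alternatives and the rule for naming genes. The lists cover naive and core pluripotency, formative and primed pluripotency, mesoderm and primitive streak, primitive and definitive endoderm, neuroectoderm, trophoblast, the 2-cell-like state, fibroblasts, p53 targets, ribosomal proteins of each subunit, assembly factors of each subunit, Polycomb complex subunits, Hox cluster genes, Polycomb-bound developmental transcription factors, the integrated stress response, the interferon response, G1/S and G2/M genes, snoRNA host genes, cholesterol synthesis, glycolysis and hypoxia, and mitochondrially encoded mRNAs. Each list with at least 3 tested members was compared with all other genes by camera (limma 3.58.1, two-sided, preset correlation between genes 0.01, adjusted over the lists). Members past the test were counted over all genes tested and again adjusted over the list alone.

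The rule names Rsl24d1, the 6 largest rises and 6 largest falls among genes past the test with an average log2 CPM of at least 3 and groups that did not overlap (clone-based, predicted and accession-type symbols left out), the 3 called members with the largest change of each list past the set test, the member with the smallest p of each other list, and 13 genes chosen in advance: Pou5f1, Nanog, Sox2, Klf4, Ezh2, Eed, Suz12, Eif6, Nmd3, Rpl24, Cdkn1a, Mdm2 and Trp53. Members named because 5 or fewer of a list moved one way were chosen after their values were seen. Single values of 2 list members that these rules would name are not reported here.

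The edgeR step was tested on simulated data made from these libraries' means and totals, with 14961 genes run. It recovered 30% of genes changed 1.25-fold, 67.3% of those changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold, and it called 0.09% of unchanged genes. In the simulation 14737 genes were unchanged and genes varied independently. In the data 6212 of 15084 genes were called, so these rates may not carry over.

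The alternatives were DESeq2 size factors, library totals and upper-quartile scaling in place of TMM, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, loess corrections for GC content and transcript length with and without that block, an adjusted p under 0.01, camera with an estimated correlation, fry, and leaving out each library in turn. Values that were not rounded were tried as an alternative chosen after seeing the data. Shares of counts in gene classes were compared by a two-sided exact permutation test, for which 3 against 3 libraries cannot give a p under 0.1. Counting intervals are at the 95% level and cover counting error only.

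Gene symbols were paired with positions, lengths and GC content of GRCm38 through GENCODE M21, and 99.78% of tested genes had a length and GC value. Genes with near-identical copies are uncertain, because estimated counts divide shared reads between copies. This applies to the Zscan4 family, to ribosomal protein genes with processed pseudogenes and to mitochondrial genes with nuclear copies. Overlapping genes on opposite strands are uncertain too, since the strand setting of the counting is not given in the sources used here.

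Lists and families added after the first results were seen are HIF targets outside glycolysis, YAP targets, actin cytoskeleton genes driven by SRF, immediate early genes, germline genes, TOP mRNAs other than ribosomal proteins, histone cluster genes, nuclear-encoded respiratory chain subunits and assembly factors, mitochondrial ribosomal proteins, proteasome subunits, and olfactory and vomeronasal receptors. Their set tests were adjusted over these 11 lists.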

Results

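Total RNA depleted of ribosomal RNA was sequenced from CGR8 mouse embryonic stem cells, which stay pluripotent in medium with serum and the cytokine LIF. The cells had received a non-targeting siRNA pool (siCtrl, n = 3) or a pool against Rsl24d1 (siRSL24D1, n = 3) and were collected after 48 hours. Library totals lay between 30943635 and 35214000 estimated counts, at which 17710 to 18201 genes had a count. Rsl24d1 encodes an assembly factor of the large ribosomal subunit. The comparison asks which transcripts differ in stem cells when this factor is reduced, with the ribosome and pluripotency as the stated interests of the study.

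In the siRSL24D1 libraries Rsl24d1 mRNA was at 0.538 of its siCtrl level. With a preset correlation between genes, 6 of 23 lists were lower: glycolysis and hypoxia (24 of 24 tested members fell), interferon response (24 of 25), cholesterol synthesis (18 of 22), G2/M (18 of 20) and the ribosomal proteins of the large (37 of 48) and small subunit (25 of 32). Higher were 9 lists: p53 targets (23 of 30 rose), Hox genes (12 of 15), the 2-cell-like state (9 of 13), neuroectoderm (6 of 12), mesoderm (8 of 17), Polycomb-bound factors (10 of 19), mitochondrial mRNAs (6 of 13) and assembly factors of the large (23 of 49) and small subunit (22 of 46). With an estimated correlation only the interferon list kept its call (adjusted p = 0.0478), and the other 14 lists were at adjusted p = 0.0505 to 0.455. That correlation was -0.0512 for Hox genes, -0.0484 for mesoderm and -0.0798 for neuroectoderm, under the preset 0.01. Correlated members therefore do not explain the lost calls of these lists. For the others that lost their call it was 0.1023 to 0.8585. Pou5f1, the core pluripotency factor, differed by 0.00 on the log2 scale between the groups, while Nanog fell by 0.49. Of 15084 genes tested, 3191 rose and 3021 fell, and 351 rose and 281 fell by at least 2-fold (edgeR, adjusted p under 0.05).

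Rsl24d1 (chromosome 9, 73113426 to 73123333, plus strand, GRCm38) was measured at 100.004 ± 2.44 CPM in siCtrl and 53.8 ± 1.74 CPM in siRSL24D1 (SD, n = 3 each). All 3 siRSL24D1 libraries, at 52.1 to 55.6 CPM, lay below all 3 siCtrl libraries, at 97.9 to 102.7 CPM. The log2 fold change was -0.89 with a standard error of 0.04 (edgeR adjusted p = 2.0e-05).

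**Figure D1:**
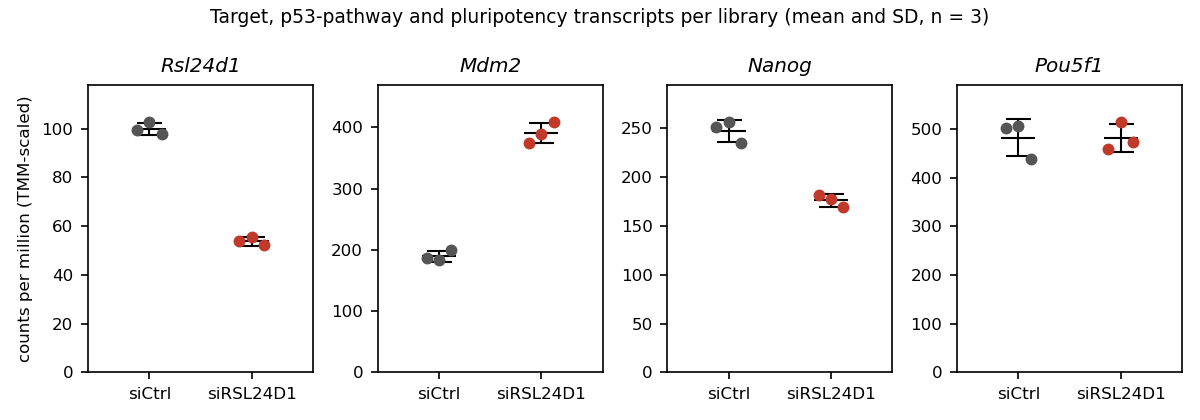
TMM-scaled CPM of Rsl24d1, Mdm2, Nanog and Pou5f1 in each library, with siCtrl in grey and siRSL24D1 in red, and the mean and SD of 3 libraries as bars. The groups do not overlap for Rsl24d1, Mdm2 and Nanog, and they overlap for Pou5f1.

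Among genes with an average log2 CPM of at least 3, the largest rise was that of Nkx1-2, a homeobox gene (chromosome 7, 132594878 to 132599637), from 2.99 ± 0.18 to 13.2 ± 1.64 CPM, a log2 fold change of 2.15 (adjusted p = 2.2e-05). Pik3r3, a regulatory subunit of PI3-kinase, rose 3.55-fold, Filip1l 3.44-fold, Anks1b 3.07-fold and Cyyr1 3.01-fold. Ptgs2, the inducible prostaglandin synthase, rose 2.89-fold. The largest fall was that of Zc3h6, a zinc finger gene (chromosome 2, 128967402 to 129018563), from 13.6 ± 0.21 to 3.04 ± 0.57 CPM, a log2 fold change of -2.17 (adjusted p = 2.2e-05). Aldoc, a glycolytic aldolase, and Pygl, the liver glycogen phosphorylase, both had a log2 fold change of -1.81. Ddx60, an antiviral helicase induced by interferon, was at -1.77, Bnip3, a hypoxia-induced mitophagy receptor, at -1.76, and Gstm3, a glutathione transferase, at -1.62. Adjusted p-values of these 12 genes ran up to 0.00137, that of Cyyr1, and the groups did not overlap for any of them.

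The p53 target genes rose as a group (median log2 fold change 0.40, camera adjusted p = 5.3e-13; adjusted p = 0.107 with an estimated correlation). Of 30 tested targets, 23 rose and 1, Sesn1, fell, over all genes tested and also adjusted over the list alone. Mdm2, which encodes the ubiquitin ligase of p53 (Mdm2 is itself a p53 target), rose from 189.7 ± 8.55 to 391 ± 16.9 CPM, a log2 fold change of 1.04. Fas, a death receptor, rose by 1.18 and Sesn2, a stress-induced sestrin, by 0.89. Cdkn1a, the p21 cell cycle inhibitor, rose by 0.41, and Trp53 itself by 0.25.

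Glycolysis and hypoxia genes fell together. All 24 tested members fell, over all genes tested and adjusted over the list alone, with a median log2 fold change of -0.89 (camera adjusted p = 2.9e-37; adjusted p = 0.0945 with an estimated correlation). Beside Bnip3, the largest falls in the list were those of Egln3, an oxygen sensor induced by hypoxia, at -1.52, and Car9, a carbonic anhydrase, at -1.45. In cholesterol synthesis, 18 of 22 tested members fell, or 20 adjusted over the list alone, and 1, Hsd17b7, rose. The list's median was -0.57 (camera adjusted p = 9.9e-18; adjusted p = 0.0633 with an estimated correlation). Insig1, a sterol sensor, was at -0.87, and Dhcr7, a late enzyme of the pathway, at -0.81.

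Interferon-response genes were at a median of -0.91, and 24 of 25 tested members fell, over all genes tested and adjusted over the list alone (camera adjusted p = 8.1e-39). This was the only fixed list past the threshold with an estimated correlation (adjusted p = 0.0478). The antiviral gene Rsad2 fell from 6.35 ± 0.59 to 1.63 ± 0.09 CPM, a log2 fold change of -1.96. Rtp4 was at -1.54 and Bst2, which tethers viruses to the cell, at -1.41. The member that did not pass was Mx1, at 0.00. Both groups had received siRNA, and untransfected cells were not analysed here.

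**Figure D2:**
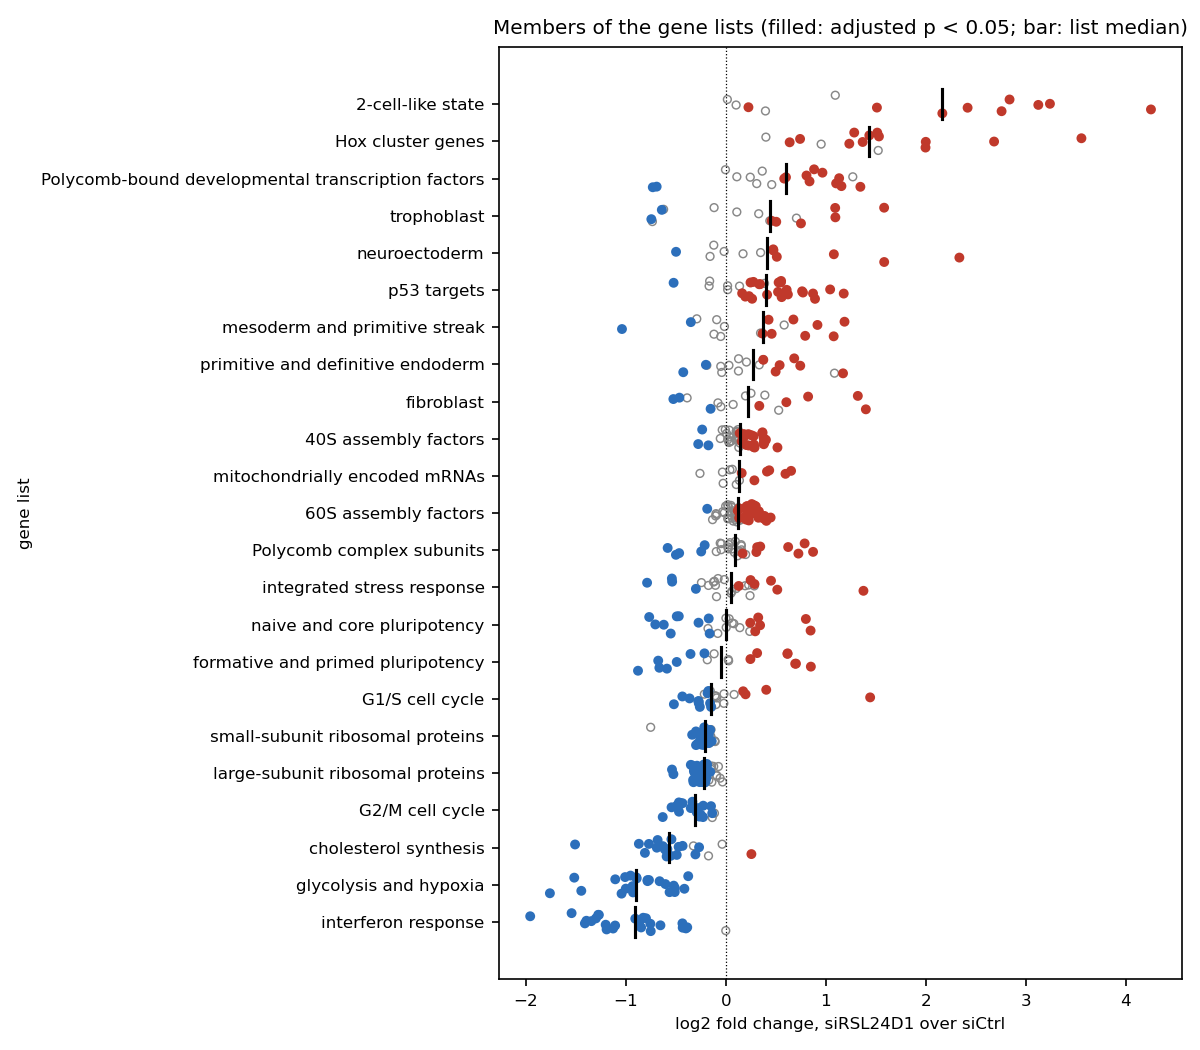
Log2 fold change (siRSL24D1 over siCtrl) of each tested member of the fixed gene lists, 1 list per line, with filled points for members past the test (red higher, blue lower), open points for the others and a bar at the list's median. All glycolysis and hypoxia members and all but 1 interferon-response member lie to the left of 0 and are filled, and the 2-cell-like and Hox lists have the highest medians, 2.17 and 1.44.

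Ribosomal protein genes fell by a small amount. Of 48 tested genes of the large subunit, 37 fell and 0 rose, or 38 and 0 adjusted over the list alone, at a median log2 fold change of -0.22 (camera adjusted p = 2.3e-07; adjusted p = 0.455 with an estimated correlation). Of 32 tested genes of the small subunit, 25 fell and 0 rose, or 30 and 0 adjusted over the list alone, at a median of -0.21 (camera adjusted p = 6.8e-05; adjusted p = 0.455 with an estimated correlation). Rpl3 fell from 2987 ± 207 to 2057 ± 90.5 CPM, a log2 fold change of -0.54, Rpl10a was at -0.52 and Rpl10 at -0.35. Among small-subunit genes, Rps20 was at -0.34, Fau at -0.30 and Rps18 at -0.30. Fau lost its call without siCtrl 1, siCtrl 2, siRSL24D1 1 or siRSL24D1 3 (adjusted p = 0.0566 to 0.0717), and Rps18 without siCtrl 2 (adjusted p = 0.0538). Rpl24, the ribosomal protein related in sequence to Rsl24d1, was at -0.19 (adjusted p = 0.036), and at -0.09 (adjusted p = 0.115) after a correction for transcript length; it also lost its call without siCtrl 1, siCtrl 2, siRSL24D1 1 or siRSL24D1 3 (adjusted p = 0.0976 to 0.148). Ribosomal protein genes took 10.6 ± 0.61% of all counts in siCtrl and 9.23 ± 0.27% in siRSL24D1 (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). In siCtrl 3 the share was 9.92%, against 10.9% and 10.996% in siCtrl 1 and siCtrl 2. The number of lower calls moved with the libraries used: it was 21 and 8 for the large and small subunit without siCtrl 1, 17 and 6 without siCtrl 2, 46 and 31 without siCtrl 3, 23 and 9 without siRSL24D1 1 and 19 and 8 without siRSL24D1 3.

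Assembly factors of the ribosome went the other way. For the large subunit, 23 of 49 tested factors rose and 1, Noc2l, fell, or 23 and 2 adjusted over the list alone, at a median of 0.12 (camera adjusted p = 0.0028; adjusted p = 0.455 with an estimated correlation). Without siCtrl 2 the number of factors that rose was 15, and without siCtrl 3 the number that fell was 5. Nifk rose by 0.45, Ddx51 by 0.41 and Brix1 by 0.39. Eif6, which keeps the large subunit from joining the small one, was at 0.21 (adjusted p = 0.0478), a call lost under DESeq2 size factors (adjusted p = 0.0633), upper-quartile scaling (0.0861) and no filter (0.0504), and without any 1 library other than siRSL24D1 3. Nmd3, the export adaptor, was at 0.09 (adjusted p = 0.128). For the small subunit, 22 of 46 tested factors rose and 3, Utp14a, Imp3 and Dimt1, fell, or 25 and 3 adjusted over the list alone, at a median of 0.14 (camera adjusted p = 0.00027; adjusted p = 0.432 with an estimated correlation). Utp20 rose by 0.52, Pwp2 by 0.40 and Dhx37 by 0.39, a call lost without siCtrl 2 (adjusted p = 0.0503) or siRSL24D1 1 (adjusted p = 0.0538). Of the snoRNA host genes, Snhg11 was the 1 tested, at -0.34 (adjusted p = 0.107), and it passed under DESeq2 (adjusted p = 0.0393) and after the length correction (adjusted p = 0.02).

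Pluripotency genes moved in both directions. Of 24 tested naive and core genes, 6 rose and 9 fell, over all genes tested and adjusted over the list alone. The median was 0.00, the mean was -0.04, and the set test was not passed (direction down, camera adjusted p = 0.246), though the list passed under fry, which asks whether members change and not whether they differ from other genes (adjusted p = 0.0307). Without siCtrl 2 or siRSL24D1 3 the number that fell was 6. Nanog fell from 247 ± 11.2 to 176 ± 6.44 CPM (adjusted p = 0.00019), and Tdgf1, a Nodal co-receptor, was at -0.62. Pou5f1 was at 482 ± 37.9 CPM in siCtrl and 482 ± 28.6 CPM in siRSL24D1 (adjusted p = 0.991), a difference whose sign changed with the scaling. Sox2 was at 0.08 (adjusted p = 0.114) and passed with library totals only (adjusted p = 0.047). Klf4 was at 0.24 (adjusted p = 0.136) and passed without siCtrl 3 (adjusted p = 0.0071). Of 18 tested formative and primed genes, 7 rose and 7 fell, over all genes tested and adjusted over the list alone (camera adjusted p = 0.987). Their median was -0.05 while the set test pointed up. Cdh2, which encodes N-cadherin, rose by 0.85.

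Several lists of developmental genes were higher. Of 15 tested Hox genes, 12 rose, or 14 adjusted over the list alone, and 0 fell, at a median of 1.44 (camera adjusted p = 2.2e-07; adjusted p = 0.0505 with an estimated correlation). Their levels stayed low: Hoxb9 rose from 0.15 ± 0.03 to 1.81 ± 0.11 CPM, a log2 fold change of 3.56, Hoxd4 by 2.68 and Hoxc13 by 2.001. Of 19 tested Polycomb-bound developmental transcription factors, 10 rose and 2, Wt1 among them, fell, or 12 and 2 adjusted over the list alone, at a median of 0.60 (camera adjusted p = 0.0063; adjusted p = 0.289 with an estimated correlation). En2, a homeobox gene of the midbrain and hindbrain, rose by 1.35, Tal1, a blood transcription factor, by 1.16 and Irx5 by 1.13. Under a filter of at least 1 CPM in at least 3 libraries, 5 Hox genes and 6 Polycomb-bound factors rose, since fewer members were tested. Without a filter, 18 of 39 Hox genes and 11 of 40 Polycomb-bound factors rose.

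Neuroectoderm markers had a median of 0.41, with 6 of 12 tested members higher and 1, Elavl3, lower, over all genes tested and adjusted over the list alone (camera adjusted p = 0.0030; adjusted p = 0.107 with an estimated correlation). Without siCtrl 2, siRSL24D1 1 or siRSL24D1 3 the number that rose was 4. Neurod1, a neuronal transcription factor, rose from 2.7 ± 0.16 to 8.10 ± 0.03 CPM, Tubb3, the neuronal tubulin, by 1.08 on the log2 scale, and Zic1, with 8 counts over the siCtrl libraries, by 2.34. Mesoderm and primitive streak markers had a median of 0.37, with 8 of 17 tested members higher and 2, Cer1 and Fgf8, lower, over all genes tested and adjusted over the list alone (camera adjusted p = 0.0050; adjusted p = 0.107 with an estimated correlation). Mixl1, a homeobox gene of the primitive streak, rose by 1.19 and Kdr, a VEGF receptor, by 1.08, while Cer1, a secreted Nodal antagonist, was at -1.04.

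In the 2-cell-like list, markers of a rare state that resembles the 2-cell embryo, 9 of 13 tested members rose and 0 fell, over all genes tested and adjusted over the list alone, at a median of 2.17 (camera adjusted p = 7.0e-07; adjusted p = 0.164 with an estimated correlation). Zscan4d rose from 0.26 ± 0.13 to 2.30 ± 0.54 CPM and Zscan4b from 0.04 ± 0.07 to 0.41 ± 0.11 CPM. Near-identical Zscan4 copies share reads, so the value of a single copy is uncertain and rises of such copies are not separate observations. Zfp352 had 2 counts over the siCtrl libraries and 45 over the siRSL24D1 libraries, a ratio of 22.9 with a counting interval from 5.97 to 194.5. With the filter of at least 1 CPM, 8 members were tested, 5 rose and the median was 1.28.

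Markers of other cell types that such cultures could hold were mixed. For primitive and definitive endoderm, 6 of 18 tested members rose and 2, Dab2 and Pdgfra, fell, over all genes tested and adjusted over the list alone, at a median of 0.27 (camera adjusted p = 0.0508; adjusted p = 0.379 with an estimated correlation). That list passed under several alternatives, with DESeq2 size factors (adjusted p = 0.0475) and fry (0.00711) among them. The number that fell was 4 after the length correction and 1 without siCtrl 2, siCtrl 3, siRSL24D1 2 or siRSL24D1 3. The number that rose was 4 under the DESeq2 test, and the median was 0.18 without siRSL24D1 2 and 0.17 under the filter of at least 1 CPM. Col4a1, a basement membrane collagen, rose by 0.75. For trophoblast, 6 of 15 tested members rose, or 7 adjusted over the list alone, and 2, Krt7 and Tead4, fell (median 0.44, camera adjusted p = 0.173; fry adjusted p = 0.013). Without siRSL24D1 3 the median was 0.25, and without siRSL24D1 2 the number that fell was 3. Cdx2, the trophectoderm factor, rose from 1.69 ± 0.08 to 5.09 ± 0.36 CPM. For fibroblasts, 5 of 16 tested members rose (Acta2, Lox, Tagln, Col3a1 and Fbn1) and 3 fell (Pdgfrb, Col1a2 and Mmp2), over all genes tested and adjusted over the list alone (median 0.22, camera adjusted p = 0.058). The list passed in several alternatives, among them the DESeq2 test (adjusted p = 0.0362), fry (0.00705) and runs without siCtrl 3 (0.0213), siRSL24D1 2 (0.0178) or siRSL24D1 3 (0.0364). Without siCtrl 3 the number that rose was 8, and without a filter the median was 0.13. Acta2, the smooth muscle actin, rose from 63.8 ± 3.94 to 159 ± 22.5 CPM.

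Polycomb complex subunits went both ways, with 8 of 30 tested members higher, or 9 adjusted over the list alone, and 5 lower in either case (median 0.09, camera adjusted p = 0.258; fry adjusted p = 0.0167). The lower members were Ezh1, Phf19, Pcgf1, Ezh2 and Suz12. Ezh1, a histone methyltransferase, was at -0.58, its relative Ezh2 at -0.25, and Suz12 at -0.21, while Eed rose by 0.31. Suz12 lost its call without siRSL24D1 2 (adjusted p = 0.0546), and the number of higher subunits was 5 without siCtrl 1, without siCtrl 2 or without siRSL24D1 1.

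G2/M genes fell: 18 of 20 tested members were lower and 0 higher, over all genes tested and adjusted over the list alone, at a median of -0.31 (camera adjusted p = 1.9e-09; adjusted p = 0.167 with an estimated correlation). Aurkb, a mitotic kinase, was at -0.63, Top2a, a topoisomerase of dividing cells, at -0.54 and Cdk1, the mitotic cyclin-dependent kinase, at -0.49. Of 25 tested G1/S genes, 11 fell, or 13 adjusted over the list alone, and 4 rose (Ccnd2, Ccnd1, Ccne2 and Tyms), at a median of -0.15 (camera adjusted p = 0.173). Ccnd2, a D-type cyclin, rose from 19.8 ± 2.38 to 53.8 ± 2.48 CPM. The number of lower G1/S genes was 7 without siCtrl 1, without siCtrl 2 or without siRSL24D1 3, that of higher ones was 2 without siCtrl 2 or siRSL24D1 3, and the list passed under limma-voom (adjusted p = 0.0171) and fry (0.0424).

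The integrated stress response list was not past the set test (median 0.05, camera adjusted p = 0.875). Of 25 tested members, 6 rose and 4 (Stc2, Phgdh, Asns and Ddit4) fell, or 6 and 7 adjusted over the list alone. With DESeq2 size factors or upper-quartile scaling, 7 fell, and without siRSL24D1 3, 4 rose. Atf3, a stress-induced transcription factor, rose from 12.03 ± 0.51 to 31.2 ± 3.70 CPM. Mitochondrially encoded mRNAs had a median of 0.14, with 6 of 13 higher and 0 lower, over all genes tested and adjusted over the list alone (camera adjusted p = 0.0063; adjusted p = 0.276 with an estimated correlation). Without siRSL24D1 1 the median was 0.08 and 4 were higher, and without siCtrl 3 or siRSL24D1 2, 1 was lower. The transcript mt-Nd3 rose by 0.65, mt-Cytb by 0.60 and mt-Nd1 by 0.43. Mitochondrial mRNAs took 2.08 ± 0.06% of counts in siCtrl and 2.20 ± 0.05% in siRSL24D1 (exact permutation p = 0.1). The 10 most counted genes took 6.37 ± 0.22% and 6.27 ± 0.15% (exact permutation p = 0.7), and the 100 most counted genes 22.004 ± 0.79% and 20.6 ± 0.40% (exact permutation p = 0.1).

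**Figure D3:**
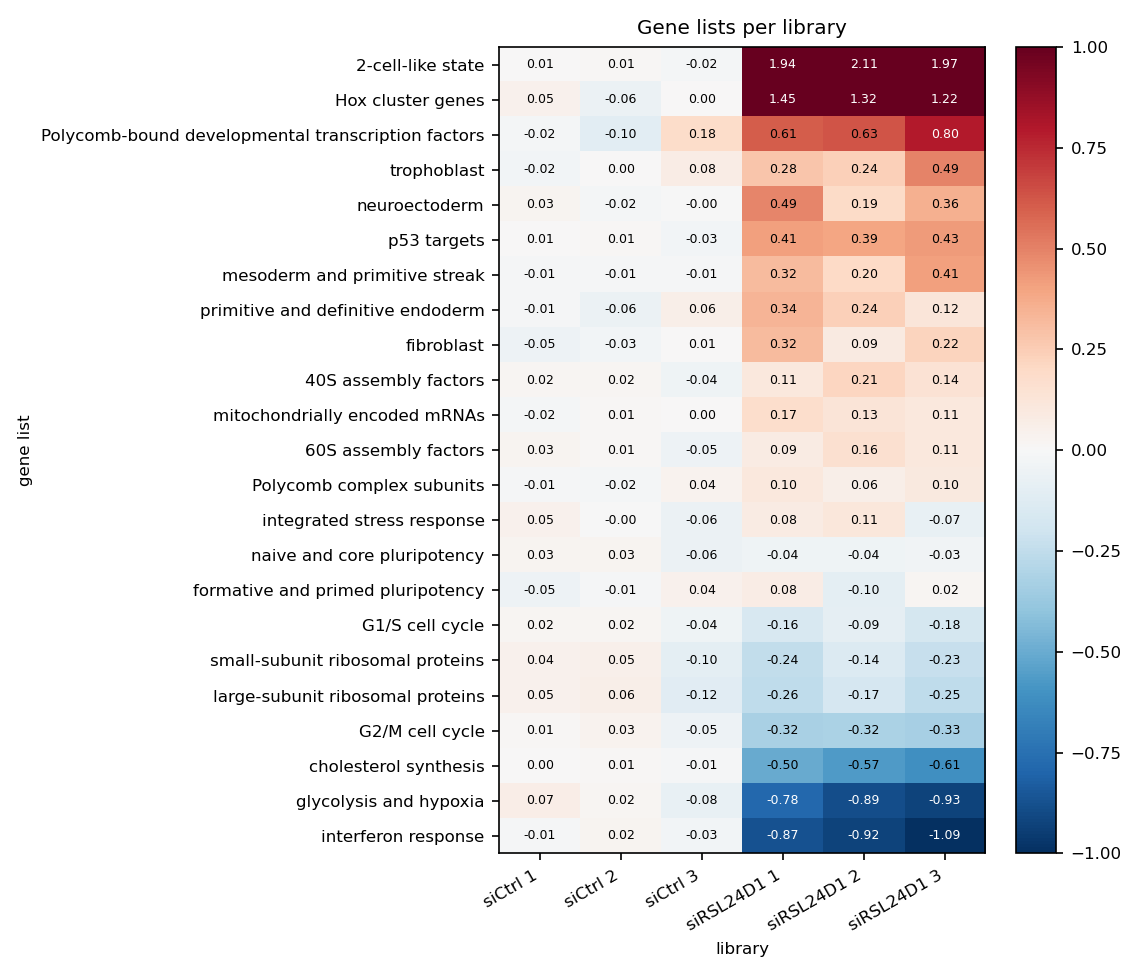
Median deviation of the members of each gene list from their siCtrl mean, in log2 CPM, with 1 column per library and a colour scale that ends at -1 and 1. The interferon-response list lies between -0.87 and -1.09 in the siRSL24D1 libraries, and the p53 target list between 0.39 and 0.43.

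The first principal component held 62.88% of the variance and separated the groups. Groups did not overlap for 53.01% of tested genes, against 10% by chance. On that component siCtrl 3 lay nearest to the siRSL24D1 libraries among the controls. With a preset correlation, 15 of the 23 lists passed the set test in the real grouping, and up to 13 passed in other splits of the 6 libraries. Every other split mixes libraries of both groups on each side, so part of the real difference may stay in it. The count of 13 is therefore not a rate of false calls.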

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

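Values that were not rounded were tried only after the data were seen; all other alternatives were planned and all were run, except that the mitochondrial share has no value once mitochondrial genes are left out. Rsl24d1 kept its direction and call under all of them. Apart from the stricter threshold, between 68.95% and 99.97% of the genes called were called again in the same direction. Without 1 library, the calls ranged from 4357 (without siCtrl 2) to 6641 (without siCtrl 3), with 2210 to 3356 higher and 2147 to 3285 lower. An adjusted p under 0.01 left 1886 higher and 1867 lower genes. Scaling moved the higher share of calls from 51.37% to between 45.05% and 56.65%. Genes at least 2-fold higher numbered 223 under the stricter filter, which tests fewer weakly counted genes. With an estimated correlation, 0 lists were higher and 1 lower past the set test, against 9 and 6 with the preset one and 13 and 8 with fry. The lists that passed under fry and not in the main test were naive pluripotency (adjusted p = 0.0307), endoderm (0.00711), trophoblast (0.013), fibroblast (0.00705), Polycomb subunits (0.0167) and G1/S (0.0424).

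Results near 0 changed direction, and the cause was not tested. Pou5f1 was at -0.0103 with DESeq2 size factors and with the DESeq2 test, -0.0276 with upper-quartile scaling, -0.0049 without a filter, -0.0043 with the GC correction, -0.0022 with that correction and the block, and between -0.0759 (without siCtrl 3) and 0.0364 without 1 library, with -0.0476 without siRSL24D1 2. Nmd3 was at -0.0086 with the length correction and -0.0073 with that correction and the block. The median of the formative list, whose set direction turned, was -0.0565 with DESeq2 size factors, -0.0734 with upper-quartile scaling, -0.052 without a filter, -8e-04 with limma-voom, -0.0558 with the GC correction, -0.0871 with the length correction, 0.0061 without siCtrl 2, and between -0.1119 (without siCtrl 1) and 0.0333 without 1 library. That of the stress response list, whose set direction also turned, was 0.06 with the block, 0.0253 without siCtrl 3, 0.0189 without siRSL24D1 2, and between -0.0249 and 0.1158 without 1 library.

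The deviations of same-numbered libraries correlated across genes at -0.218, 0.144 and 0.168, so not every pair deviated together, and only siCtrl 2 and siRSL24D1 3 correlated best with their own number. The main fit had been planned without pairs, and these correlations do not decide whether the labels' replicate numbers are pairs. With the replicate number as a block, 3327 genes were higher and 3104 lower, and the fibroblast (adjusted p = 0.0342) and endoderm (0.0292) lists and Snhg11 (0.041) passed.

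Depth limits single weakly counted genes: the 2 siCtrl counts of Zfp352 give a ratio interval of 5.97 to 194.5. In the simulated comparison, where most genes were unchanged, 67.3% of genes changed 1.5-fold were recovered over all count levels. Of the 10 splits of the 6 libraries, 1, the real one, gave 6212 called genes, and the highest other gave 182. For lists past the set test the count was also 1, with 15 lists against 13. Since 10 splits cannot give a share under 0.05, they are too few to decide.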

Other observations

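The lists and families in this part, the test of genomic DNA on receptor genes, the tests of a rise of silent genes with their limits and the length test of the ribosomal protein lists were chosen after related results were seen; members named here were also chosen after their values were seen. The receptor tests replace versions on all receptors, with a limit of 0.1 CPM on the receptors and, for genomic DNA, with tested members only (ratio under 0.1 there too); the 0.1 CPM version had left a rise of silent genes as a possible cause for the whole germ-layer, trophoblast and Polycomb-bound lists, so the comparison is given at 6 limits. Expressed members were first split by the mean of all libraries, then by siCtrl alone. Actin cytoskeleton genes driven by the transcription factor SRF rose together: 13 of 14 tested members rose and 0 fell, at a median log2 fold change of 0.45 (camera adjusted p = 5.2e-07; adjusted p = 0.337 with an estimated correlation). Flna, a filamin, rose by 0.51, Vcl, the focal adhesion protein vinculin, by 0.45 and Srf itself by 0.42. Of 18 immediate early genes, 11 rose and 3 (Maff, Klf10 and Ier3) fell, at a median of 0.46 (camera adjusted p = 0.0046; adjusted p = 0.337 with an estimated correlation). Jun rose by 0.74, Egr1 by 0.79 and Myc by 0.53. Of 22 YAP targets, 9 rose and 4 (Ankrd1, Igfbp3, Nuak2 and Nt5e) fell, with no call in the set test (camera adjusted p = 0.194).

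Of 66 tested histone cluster genes, 4 (Hist1h2aa, Hist1h2an, Hist1h2ba and Hist2h3c1) rose and 15 fell, at a median of -0.15 (camera adjusted p = 0.0341; adjusted p = 0.863 with an estimated correlation). Of 86 nuclear-encoded respiratory chain subunits and assembly factors, 3 (Atp5l, Ndufaf4 and Ndufb2) rose and 22 fell, at a median of -0.06 (camera adjusted p = 0.0358; adjusted p = 0.863 with an estimated correlation). Mitochondrial ribosomal proteins, with 10 higher and 9 lower of 78, and proteasome subunits, with 6 higher and 5 lower (Psma7, Psmb1, Psmb10, Psmb8 and Psmb9) of 40, were not past the set test (camera adjusted p = 0.883 for both). Neither were germline genes, with 3 higher (Hormad1, Taf7l and Tex19.1) and 3 lower (Mov10l1, Sycp3 and Tuba3a) of 16 (camera adjusted p = 0.611). Olfactory and vomeronasal receptor genes had 18 higher and 4 lower (Olfr127, Olfr1388, Olfr718-ps1 and Vmn2r10) of 272 tested, or 2 and 4 adjusted over the list alone (median 0.21, percentile 100 of matched lists, camera adjusted p = 0.0607).

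All 12 tested predicted genes in repeat-rich regions on chromosomes 2, 9 and 14 rose, at a median log2 fold change of 1.75. Gm10800 (chromosome 2, 98666547 to 98667301, GRCm38) rose from 311.9 ± 69.3 to 1072 ± 448 CPM. Their summed level was 721.6, 688.7 and 983 CPM in siCtrl 1 to 3 and 2497, 3736 and 1619 CPM in siRSL24D1 1 to 3. Such near-identical copies share reads, so the value of a single copy is uncertain and the 12 rises are not separate observations.

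Hox, 2-cell-like, germ-layer, trophoblast and Polycomb-bound genes had a median log2 fold change of 0.50 over 109 members, 60 of which were at 1 CPM or more in siCtrl and germ-layer, trophoblast or Polycomb-bound. That median lay at percentile 100 of 10000 random lists matched on mean expression. This argues against a rise shared by all genes of the same expression level. The 272 tested receptors also lay at percentile 100, so this test does not set the lists apart from a rise of silent genes. Carried-over genomic DNA is argued against for the 100 list members under 1 CPM. The mean rise per kilobase of receptor genes under 1 CPM was 0.0494 of the median rise of these members. No count filter was used on either (0.0330 to 0.0613 without 1 library). At a limit of 5 CPM the ratio was 0.134, and up to 0.196 without 1 library. That is not under the bound of 0.1, so carried-over DNA stays open at that limit. It was not tested for the 12 predicted genes in repeat-rich windows, which also rose. The rise was not confined to members under 1 CPM in siCtrl. Of the 60 germ-layer, trophoblast and Polycomb-bound members of at least 1 CPM there, 27 rose and 9 fell, at percentile 100 of matched lists. This describes where the rise was seen and does not test its cause. Whether a rise shared with the receptors reaches these members stays open. A limit of 5 CPM takes in some of them. There the members' lowest summed log2 ratio without 1 library was 0.3834, against the receptors' highest of 0.386. A rise of silent genes of any kind is argued against for the Hox and 2-cell-like members under 1 CPM. Their summed log2 ratios of 1.5491 and 1.62 exceeded the receptors' 0.22, as they did at all 6 limits from 0.1 to 5 CPM. For the other members such a rise stays open and may account for at least part of theirs. The ratio of those under 1 CPM was 0.5736, against the receptors' 0.22. At all 6 limits the members' ratio over all libraries lay above the receptors' highest ratio without 1 library. Leaving out 1 library, the members' lowest ratio stayed above it at 4 of the 6 limits only. A response to reduced Rsl24d1 remains a hypothesis, and an effect of the siRNA pool on other targets was not tested.

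Glycolysis and hypoxia (24 of 24 fell), cholesterol (18 of 22) and interferon genes (24 of 25) were lower, with adjusted p = 0.0945, 0.0633 and 0.0478 with an estimated correlation. A trend with GC content or transcript length as the cause is argued against, since each list kept at least 1.005 of its median after the GC correction and at least 0.993 after the length correction; the trends removed from single genes were -0.002 to 0.061 for GC and -0.143 to 0.447 for length. For glycolysis and hypoxia, lower activity of the hypoxia-inducible factor HIF is a candidate explanation: of 23 HIF targets outside that list, 18 fell and 1 (Pfkfb4) rose, at a median of -0.443 (camera adjusted p = 3.0e-11; adjusted p = 0.0302 with an estimated correlation), with Ppp1r3c at -1.83 and Hif3a at -1.13. Oxygen supply, cell density and the siCtrl pool's own effect on interferon genes stay open, as no untransfected cells or densities were analysed here.

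Ribosomal protein genes were lower (37 of 48 and 25 of 32) and assembly factors higher (23 of 49 and 22 of 46), with adjusted p = 0.455, 0.455, 0.455 and 0.432 with an estimated correlation. A GC trend is argued against, since the lists kept at least 0.904 of their medians after the correction. A length trend is argued against for the assembly factors, which kept at least 1.012, and as the whole cause for the ribosomal protein genes, which kept at least 0.708, with 34 large-subunit and 22 small-subunit genes still lower; it may account for part of their fall. Whether all mRNAs with a TOP motif, a translation control element at the 5' end, moved with them stays open, since 19 others had a median of -0.0864 with 8 lower and 0 higher, short of the set test's threshold (camera adjusted p = 0.082). The ribosomal protein share of siCtrl 3 (9.92%) lay between those of the other controls and the siRSL24D1 libraries. Leaving it out could therefore only enlarge the fall, so the medians without it, -0.28 and -0.26, decide nothing about the cause. Pluripotency or growth state was not separated from the reduction of Rsl24d1.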
